A study of Mus musculus with 6 samples.

How the data were processed

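The series compared adipose tissue of mouse offspring at 32 weeks of age. The mothers of 3 offspring samples ate a chromium restriction diet and the mothers of 3 ate a control diet, per the labels. Total tissue RNA was labelled with biotin and hybridised to 1-colour arrays, 1 array per sample, per the labels. The labels number the samples within each group but do not say that they came from separate animals or litters, so p-values measure the spread between these samples only. Neither the sex of the offspring nor the fat depot is given in the sources used here.

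The deposited value table holds 33793 probe sets on 6 arrays. The values were taken to be on a log2 scale, from their range of 3.49 to 14.86 and array medians of 5.44 to 5.57; the log base, the summarisation and the normalization that the authors used are not given in the sources used here. Because the quartiles of the 6 arrays lay close together, no further normalization was applied to the deposited log2 values in the reported comparison. All 6 value columns were used.

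Probe sets were named through the platform annotation supplied for this work. It gave 1 gene symbol for 23521 probe sets, several for 1814 and none for 8458, and those without a single symbol were left out of the gene-level test. For each of the 22180 genes the probe set with the highest mean over the 6 arrays was tested, with no filter on dim probe sets. Of these genes, 21994 were found by Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, and 0 of their symbols differed there. No genome build is named for the arrays, so no coordinates are given.

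The text of the deposited values was also examined. Nearly all of the 202758 values were written as the shortest decimal form of a single-precision number. The other 183 values carried further digits, and they lay in 64 probe sets. Of these values 149 were on chromium restriction arrays and 34 on control arrays. Such probe sets are called rows with extra digits here; what was done to them before deposit is not given in the sources used here.

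Group differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, as chromium restriction minus control, two-sided, with Benjamini-Hochberg adjustment over all 22180 genes. Calls were made at an adjusted p of 0.05. Genes with an unadjusted p under 0.05 and at least a 1.5-fold difference were counted as a description. Lists of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Of 37 lists, 21 covered pathways and 16 covered cell types, other tissues and sex-linked genes; 35 had at least 5 measured members and were tested, the sex-linked list being left out. The erythroid list had 2 measured members and was not tested. Values are given as mean ± SD over 3 arrays, and SE denotes limma's standard error of a log2 difference. With 3 arrays per group, their number limits the precision.

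The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 12 genes with the highest and the 12 with the lowest log2 difference among genes past an adjusted p of 0.05, leaving out predicted loci, small RNAs and olfactory or vomeronasal receptors; up to 4 members of each list with the smallest p; and a fixed set of adipose and insulin-related genes. Alternatives fixed at the same time were quantile normalization, median centring, a filter on genes dimmer than the median gene, eBayes with trend and robust options, array weights, the mean of a gene's probe sets, the replicate number as a block, leaving out each array in turn, all probe sets as tested units, and camera with an estimated correlation. Alternatives chosen after seeing the data left out the rows with extra digits, set the 183 values to missing, used the mean of 7 liver genes as a covariate, combined the first of these with the covariate, or left out the 2 arrays rich in liver transcripts. The mean of the 7 liver genes was 11.33 and 10.90 in chromium restriction replicates 1 and 3, and 6.55 in replicate 2. In the controls it was 6.56 to 6.94, so with this covariate the group difference rests mostly on replicate 2.

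The scripts were tested on simulated data of 22180 genes and 3 arrays against 3, with 200 changed genes in each of 5 runs. At a change of 1 log2 unit 98.6% of changed genes were recovered, and at 2 log2 units 100%, with 5.6% of calls false. A list of 20 genes shifted by 0.3 log2 units was called in 5 of 5 runs, and 0 of 145 unshifted lists were called. The noise of both simulated groups was drawn from the moderated SD of the 3 control arrays. It left out the spread between chromium restriction arrays, of which 2 were rich in liver transcripts and 1 held intestinal transcripts. The recovery rates therefore do not carry over to the measured comparison. The simulated genes varied independently and the lists were random. In the measured data the estimated correlation within a list was up to 0.66, for B and plasma cell markers. The simulation therefore does not show how often the preset correlation gives false list calls here. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.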

Results

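Gene expression was measured with 6 arrays in adipose tissue of mouse offspring aged 32 weeks. Chromium is a trace metal of the diet. The design asks how offspring adipose differs when the mother was fed a chromium restriction diet (3 arrays) rather than a control diet (3 arrays). Array medians ran from 5.44 to 5.57 on the log2 scale. The correlation between arrays, across probe sets, ran from 0.95 to 0.99.

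In the gene-level comparison 43 of 22180 genes passed an adjusted p of 0.05 in limma, 20 higher and 23 lower in the chromium restriction group. Of these 43 genes, 40 lay in rows with extra digits, in which 1 to 5 of the 6 values were written differently from the rest of the deposited table. The other 3 were Apoa4, Fabp2 and Cyp3a13, all higher in the chromium restriction group. Rows with extra digits made up 0.234% of the tested genes (52 of 22180) and 93.0% of the called ones. When they were left out, 0 genes passed in limma, with a smallest adjusted p of 0.0732, while 1264 genes had an unadjusted p under 0.05 where 1106 would be expected by chance. Calls in these rows are given as deposited values, apart from the other results.

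Several genes in rows with extra digits were listed at higher values in the chromium restriction group. Pparg, the nuclear receptor that drives adipocyte differentiation, was listed at 12.41 ± 0.08 against 10.43 ± 0.04 (log2, SD, n = 3 per group), a 3.95-fold difference. Pdpk1, the kinase that phosphorylates Akt downstream of insulin, was 4.54-fold higher, and Jund, a subunit of the AP-1 transcription factor, was 4.98-fold higher. Retn, which encodes the adipokine resistin, was listed 2.86-fold higher, the sterol regulator gene Srebf1 2.11-fold higher, the de novo DNA methyltransferase gene Dnmt3b 2.98-fold higher and Cebpa, another adipocyte transcription factor, 1.77-fold higher. Inpp5a, Myo5b, Cnn3 and Plpp3 were also among the 12 highest, with log2 differences of 1.36 to 1.78.

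Other genes in such rows were listed at lower values. Hadh, a dehydrogenase of mitochondrial beta-oxidation, was at 10.39 ± 0.29 against 12.10 ± 0.14 (SD, n = 3), 3.27-fold lower in the chromium restriction group. The acyltransferase genes Agpat3 and Dgat1 were 2.79-fold and 2.39-fold lower. Adipoq, which encodes adiponectin, was 2.33-fold lower, and its receptor gene Adipor1 was 3.05-fold lower. Ppard, Asah2, Polr3gl, Mcpt2, Ivd, Kdsr and Sgpl1 completed the 12 lowest, with log2 differences of -1.30 to -1.06. Il6, which encodes interleukin 6, was listed at 3.51 ± 0.03 against 4.50 ± 0.01. The Il6 values of the 3 chromium restriction arrays lay 0.73 to 0.79 below the lowest value of any probe set other than Il6 and Retn on the same array, and the Retn values lay 0.96 to 0.98 above the highest.

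**Figure D1:**
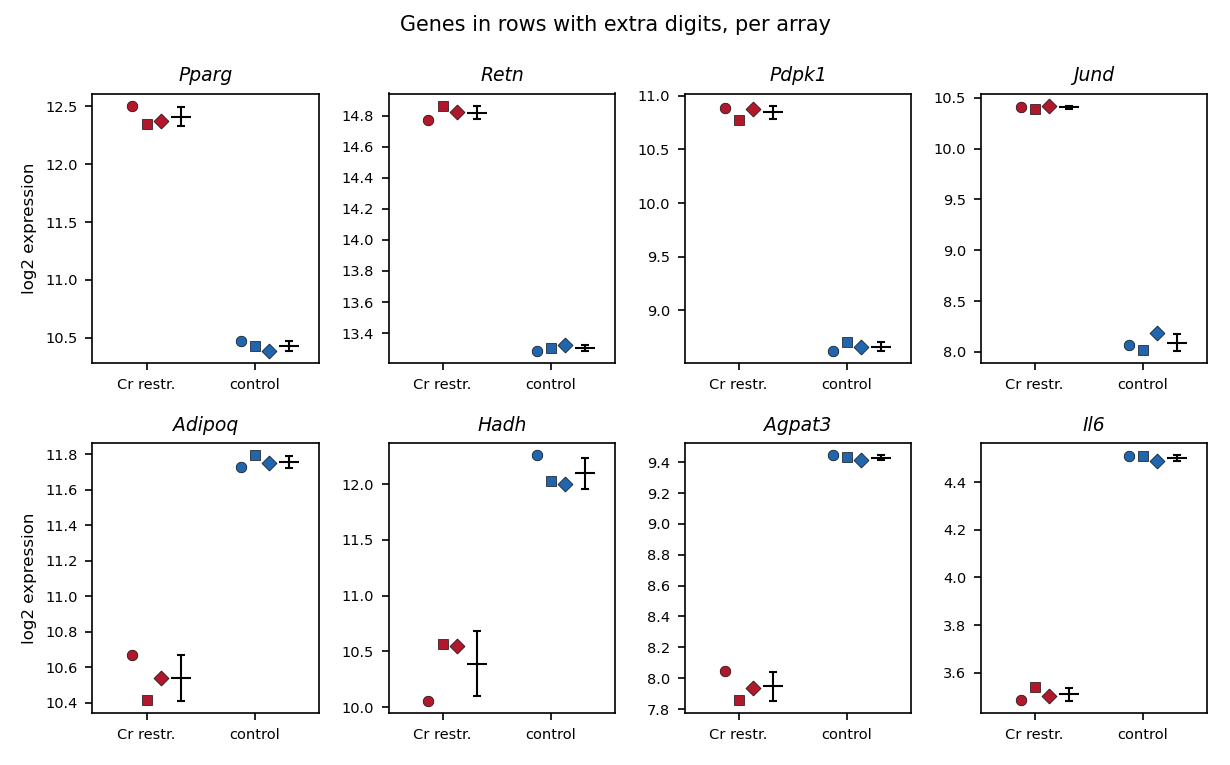
Log2 expression (vertical axis) of 8 genes in rows with extra digits, for the chromium restriction arrays (red) and control arrays (blue); circles, squares and diamonds are replicates 1, 2 and 3, and the black bars are the group mean with SD. The replicates of a group lie close together, as for Jund at 10.41 ± 0.02 against 8.09 ± 0.08, and the vertical axes do not start at 0.

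Over the 64 rows with extra digits the median absolute log2 difference between groups was 1.09, against 0.0753 in the other probe sets. The largest median among 10000 random sets of 64 other probe sets of like mean level was 0.254. The median SD within groups was 0.0902 in these rows and 0.140 elsewhere. A few of these genes had another probe set written like the rest of the table. For Lpl, lipoprotein lipase, the row with extra digits differed by 0.96 and a brighter probe set, at a mean of 13.23, by -0.055. For Jund the 2 probe sets differed by 2.32 and 0.26, and for Coro1c by 1.11 and 0.12. The sign was opposite for Gpr155, at 1.25 in the row and -0.17 in a probe set at a mean of 7.15. It was also opposite for Tnpo3, whose row is shared with Irf5, at 2.62 and -0.36.

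**Figure D2:**
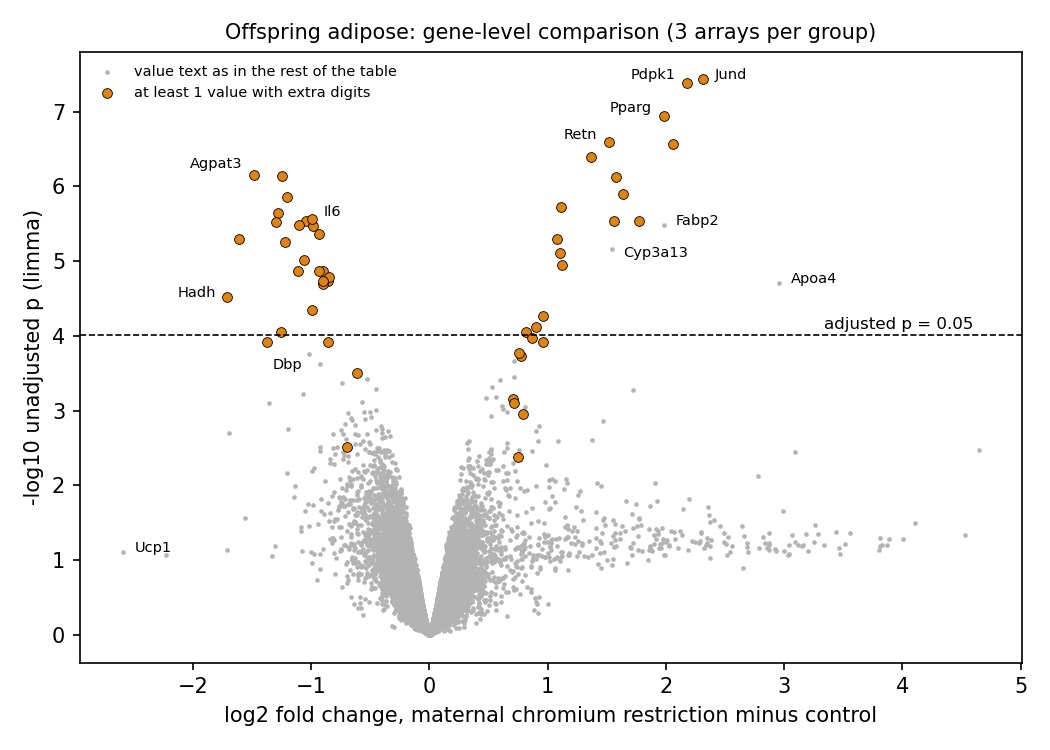
Each point is 1 of 22180 genes, with the log2 difference between groups on the horizontal axis and the -log10 of limma's unadjusted p on the vertical axis. Orange points are the 52 genes in rows with extra digits, and 40 of them lie above the dashed line at an adjusted p of 0.05 together with Apoa4, Fabp2 and Cyp3a13.

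Outside these rows, 3 genes known from intestine and liver passed. Apoa4, an apolipoprotein of chylomicrons, was at 9.90 ± 0.43 against 6.95 ± 0.33 (SD, n = 3), 7.75-fold higher in the chromium restriction group (adjusted p = 0.0120). Fabp2, the intestinal fatty acid binding protein, was at 7.25 ± 0.09 against 5.27 ± 0.23 (SD, n = 3, adjusted p = 0.00358), and the cytochrome P450 gene Cyp3a13 was at 6.21 ± 0.18 against 4.67 ± 0.10 (SD, n = 3, adjusted p = 0.00587). In each control Fabp2 lay below the array median (5.44 to 5.55) and Cyp3a13 below the lower quartile (4.75 to 4.82). The level of the background is not given in the sources used here, so no fold is stated for these 2 genes. Their log2 differences below are between listed values only. All 3 were higher in 3 of 3 chromium restriction arrays than in any control. Their log2 differences did not depend on the rows with extra digits, but without those rows their adjusted p became 0.143 for Apoa4, 0.0732 for Fabp2 and 0.0761 for Cyp3a13. Leaving out a control array ended the call of Apoa4 and Cyp3a13 each time: adjusted p was 0.0935, 0.0533 and 0.122 for Apoa4, and 0.0526, 0.0563 and 0.0567 for Cyp3a13, without controls 1, 2 and 3. With the liver genes as covariate the adjusted p was 0.0791 for Apoa4, 0.0317 for Fabp2 and 0.0457 for Cyp3a13, with log2 differences of 2.91, 1.90 and 1.55. Without both arrays rich in liver transcripts, 1 array against 3, the log2 differences were 2.95, 1.88 and 1.57. Both settings rest mostly on chromium restriction replicate 2, which held intestinal transcripts (Sis at 7.09, Muc13 at 7.55). Replicates 1 and 3 held liver transcripts. RNA of intestine or liver in these arrays therefore cannot be told apart from an effect of maternal diet on these 3 genes.

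Transcripts of other tissues differed between arrays of 1 group. Alb, which encodes albumin, was at 13.72 and 13.55 in chromium restriction replicates 1 and 3, at 9.17 in replicate 2 and at 9.37 to 9.98 in the controls. From the list of pancreas and liver markers 7 liver genes were taken as a set: Alb, Apoa1, Apoa2, Apoh, Ttr, Serpina1a and Fgb. Cyp2e1, also on that list, was not in the set. All 7 were above the highest control in both replicates 1 and 3, and 1 of 7 was in replicate 2. The whole list rose (camera adjusted p = 0.0266, 16 measured members), with 9 members higher, 7 lower and a median log2 difference of 0.17. Over all genes 0 members passed, and 1 rose and 1 fell when adjusted over the list alone. With an estimated correlation the list's adjusted p was 0.698. Without chromium restriction replicate 1 its adjusted p was 0.251, without control replicate 1 0.0631 and without control replicate 3 0.142. Replicate 2 instead held transcripts of the intestinal epithelium, chosen after their values were seen: Sis, sucrase-isomaltase, was at 7.09 there and at 4.53 to 4.62 elsewhere, and Muc13, a mucin, at 7.55 and at 4.85 to 5.02 elsewhere. A first principal component that held 60.5% of the variance set chromium restriction replicates 1 and 3 apart from the other 4 arrays.

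**Figure D3:**
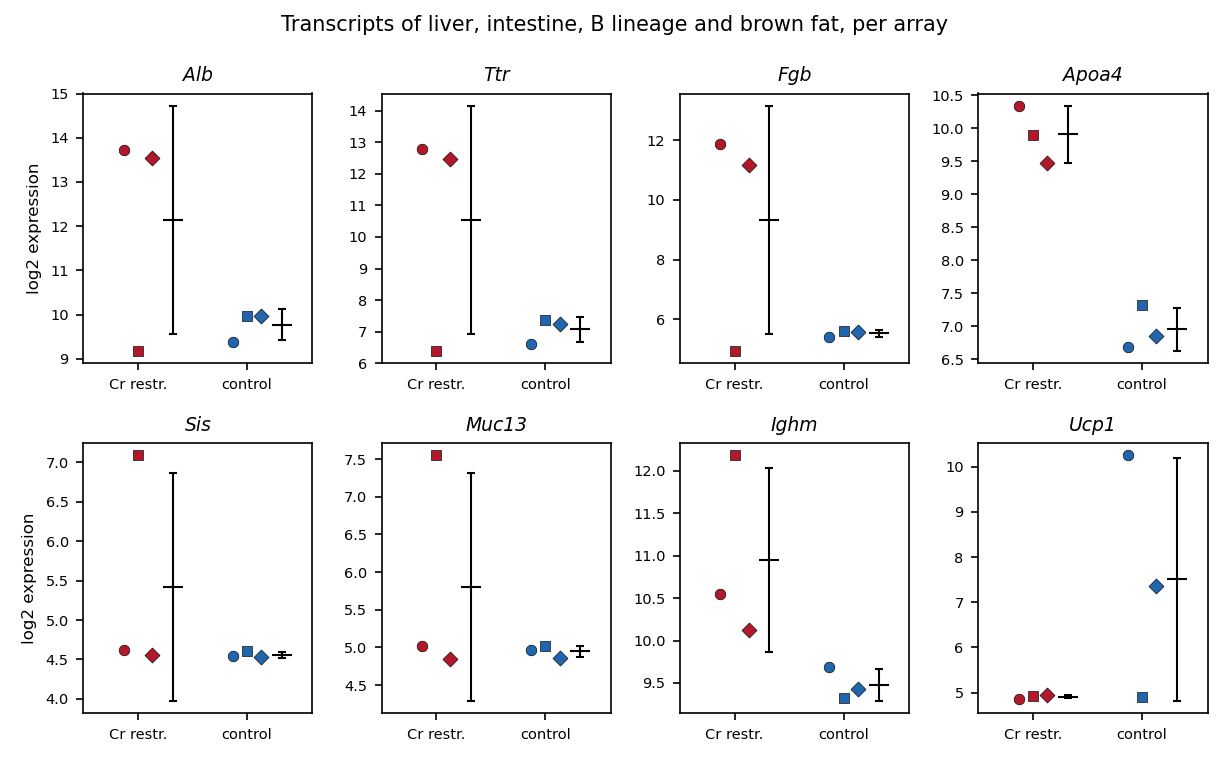
Log2 expression (vertical axis) of transcripts known from liver (Alb, Ttr, Fgb), intestine and liver (Apoa4), intestine (Sis, Muc13), B lineage cells (Ighm) and brown fat (Ucp1) in chromium restriction (red) and control arrays (blue); circles, squares and diamonds are replicates 1, 2 and 3, and the black bars are the group mean with SD. Alb is high in chromium restriction replicates 1 and 3, Sis in replicate 2 and Ucp1 in control replicate 1, and the vertical axes do not start at 0.

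Of the 35 lists tested, 16 passed an adjusted p of 0.05 with camera's preset correlation, 9 upward and 7 downward, and 0 passed with an estimated correlation. In the list of triglyceride synthesis 15 of 16 members were lower in the chromium restriction group (adjusted p = 1.02e-12), and the 4 that passed over all genes, Agpat3, Dgat1, Gpat4 and Slc27a1, all lay in rows with extra digits; 6 fell when adjusted over the list alone. With an estimated correlation the adjusted p was 0.150 for this list. Oxidative phosphorylation genes, which encode respiratory chain subunits, fell as a group, with 41 of 43 lower, a median log2 difference of -0.24 and none in a row with extra digits (adjusted p = 1.02e-12, and adjusted p = 0.433 with an estimated correlation). Among them Sdhb differed by -0.38 ± 0.09 and Uqcrc1 by -0.39 ± 0.10 (log2, SE, n = 3), and 0 of 43 members passed the test over all genes or adjusted over the list alone. The list mean was 9.03, 8.91 and 9.08 in control replicates 1, 2 and 3, and 8.65, 8.83 and 8.83 in chromium restriction replicates 1, 2 and 3. Ucp1, a brown fat gene, was raised in control replicates 1 (10.25) and 3 (7.37) but not 2 (4.89). Without control replicate 1 the camera adjusted p was 4.09e-10, and without control replicate 3 it was 2.01e-07. Brown fat in these controls was not tested as a cause of the fall. In fatty acid beta-oxidation 18 of 22 members were lower (adjusted p = 9.01e-10, and adjusted p = 0.182 with an estimated correlation); Hadh and Acads, both in rows with extra digits, fell over all genes and 10 members fell when adjusted over the list alone. Cpt2, a carnitine palmitoyltransferase, differed by -0.40 ± 0.08 and Decr1 by -0.44 ± 0.09 (SE, n = 3). The mean of this list was 9.77 in control replicate 1, the array with the highest Ucp1 (10.25), 9.35 and 9.44 in control replicates 2 and 3, and 9.04 to 9.20 in the chromium restriction arrays; without control replicate 1 its adjusted p was 5.51e-07. In chromium restriction replicate 2, where liver transcripts were at control level, the mean log2 difference from the controls was -0.35 for triglyceride synthesis, -0.18 for oxidative phosphorylation and -0.48 for beta-oxidation. The -0.35 includes 4 rows with extra digits, Agpat3 at -1.57, Dgat1 at -1.40, Gpat4 at -0.94 and Slc27a1 at -0.86. The -0.48 includes 2 such rows, Hadh at -1.53 and Acads at -0.94. Without the rows with extra digits and with the liver genes as covariate, the mean for triglyceride synthesis was -0.098 (camera adjusted p = 0.154).

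Glycolysis, de novo lipogenesis and lipolysis fell as lists. Of 21 glycolysis and glucose uptake genes 18 were lower (adjusted p = 1.31e-07, and adjusted p = 0.539 with an estimated correlation), and 5 fell when adjusted over the list alone. Ldhb, a lactate dehydrogenase subunit, differed by -0.54 ± 0.10 and Gys1, glycogen synthase, by -0.99 ± 0.25 (SE, n = 3). In de novo lipogenesis 16 of 20 members were lower (adjusted p = 0.0167, and adjusted p = 0.698 with an estimated correlation). Srebf1, in a row with extra digits, was the 1 member past the test over all genes, and it was higher; adjusted over the list alone 1 rose and 2 fell. Acacb, an acetyl-CoA carboxylase, differed by -1.36 ± 0.23 (SE, n = 3) with an adjusted p of 0.260. Lipolysis fell with 10 of 14 members lower (adjusted p = 0.0371, and adjusted p = 0.698 with an estimated correlation) and 0 members past the test in either way. In replicate 2, where liver transcripts were at control level, the mean log2 difference was -0.0906 for glycolysis, 0.0667 for lipogenesis and -0.15 for lipolysis. The mean of the lipolysis list was 9.51 in chromium restriction replicate 1, 9.83 in replicate 2 and 9.86 in replicate 3. With the liver genes as covariate the adjusted p was 0.0818 for glycolysis and 0.125 for lipolysis, and the mean for lipogenesis turned to 0.0131. With that covariate and without the rows with extra digits, in which Srebf1 lay, the mean for lipogenesis was -0.0443 (camera adjusted p = 0.514). Without both arrays rich in liver transcripts the adjusted p for glycolysis was 0.182 and the mean for lipogenesis turned to 0.0667. The lipogenesis call was also lost without chromium restriction replicate 1 (adjusted p = 0.0768) or 3 (0.0842) and without control replicate 2 (0.0807) or 3 (0.0604). The lipolysis call was lost without chromium restriction replicate 1 (0.0817) or 2 (0.0987) and without control replicate 3 (0.223), with median centring (0.0681), with the filter on dim genes (0.0508) and with array weights (0.243).

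Immediate early genes, transcription factors and phosphatases induced within minutes of a stimulus, rose as a list. Of 23 members 19 were higher (adjusted p = 9.38e-10, and adjusted p = 0.150 with an estimated correlation), with Jund, in a row with extra digits, past the test over all genes, and 7 rising and 1 falling when adjusted over the list alone. Fos differed by 1.09 ± 0.23, Ccn1 by 0.90 ± 0.25 and the phosphatase gene Dusp1 by 0.56 ± 0.14 (log2, SE, n = 3). The mean log2 difference of the list was 0.37 in chromium restriction replicate 2. Without rows with extra digits the list's adjusted p was 1.52e-07.

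Immune cell markers rose as lists, in part through chromium restriction replicate 2. Dendritic cell markers were higher in 11 of 12 members (adjusted p = 2.81e-05, and adjusted p = 0.182 with an estimated correlation), with H2-Ab1 and H2-Aa, class II histocompatibility genes, differing by 0.32 ± 0.08 and 0.37 ± 0.11 (SE, n = 3). Macrophage markers were higher in 19 of 23 (adjusted p = 0.000284, and adjusted p = 0.698 with an estimated correlation), and 1 rose when adjusted over the list alone; Mpeg1 differed by 0.71 ± 0.10 (SE, n = 3). The macrophage call was lost without chromium restriction replicate 1 (adjusted p = 0.0887) or control replicate 1 (0.0974) and with array weights (0.0548). T and NK cell markers rose (adjusted p = 7.76e-05) and so did B and plasma cell markers (adjusted p = 0.00835), each with an adjusted p = 0.698 with an estimated correlation. Without chromium restriction replicate 2 the mean of T and NK markers was -0.0018, against 0.27 with it, and their adjusted p was 0.804, and the mean of B and plasma markers turned to -0.10 (adjusted p = 0.362); the adjusted p of the B and plasma markers was 0.0589 without control replicate 1 and 0.282 with array weights. In replicate 2, which held intestinal transcripts, 15 of 16 B and plasma markers had their highest value, among them Ighm, which encodes the immunoglobulin M heavy chain.

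Extracellular matrix, cell cycle and mesothelium lists also rose. Matrix genes were higher in 28 of 36 (adjusted p = 3.41e-05, and adjusted p = 0.539 with an estimated correlation), with Mmp12, a macrophage elastase, differing by 1.41 ± 0.38 and Ccn2 by 0.73 ± 0.22 (SE, n = 3). Cell cycle genes were higher in 26 of 29 (adjusted p = 1.53e-05, and adjusted p = 0.698 with an estimated correlation), with Cdk1 differing by 0.39 ± 0.10 (SE, n = 3). Mesothelial markers were higher in 11 of 14 (adjusted p = 0.0266, and adjusted p = 0.698 with an estimated correlation). None of these 3 lists had a member past the test over all genes or adjusted over the list alone. With the liver genes as covariate the adjusted p was 0.154 for matrix genes and 0.405 for mesothelium, and without both arrays rich in liver transcripts it was 0.0868 and 0.281; the cell cycle call was lost without chromium restriction replicate 2 (adjusted p = 0.0623). The mesothelium call was lost without chromium restriction replicate 1 (0.0735) or 2 (0.0623), and without control replicate 1 the list passed in the opposite direction, with a mean of -0.16 (adjusted p = 0.0215).

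Circadian clock genes of opposite phase differed in opposite directions. Dbp, an output gene of the clock, was at 9.07 ± 0.05 against 10.10 ± 0.24 (log2, SD, n = 3), 2.03-fold lower in the chromium restriction group, with an adjusted p of 0.0789. Per3 differed by -0.82 ± 0.16, while the activators Arntl and Npas2 differed by 0.81 ± 0.14 and 0.66 ± 0.11 (SE, n = 3). Of 17 measured clock genes 0 passed over all genes, and 3 rose and 7 fell when adjusted over the list alone. The list fell (adjusted p = 0.0336, and adjusted p = 0.698 with an estimated correlation), although members of both directions are in it. Its call was lost without chromium restriction replicate 1 (adjusted p = 0.166) or 2 (0.173), without control replicate 1 (0.224), with median centring (0.0632), with array weights (0.191), with the liver genes as covariate (0.102) and without both arrays rich in liver transcripts (0.107).

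**Figure D4:**
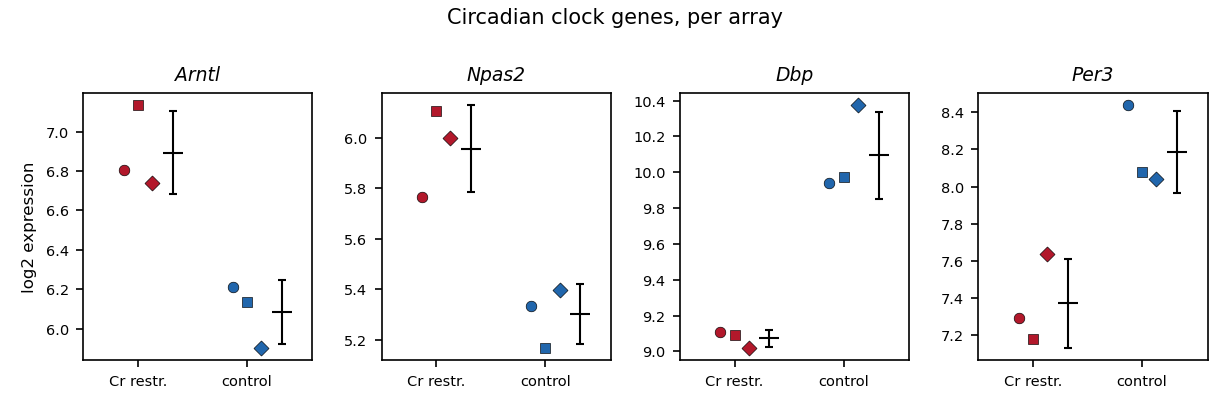
Log2 expression (vertical axis) of 4 circadian clock genes in chromium restriction (red) and control arrays (blue); circles, squares and diamonds are replicates 1, 2 and 3, and the black bars are the group mean with SD. Arntl and Npas2 are higher and Dbp and Per3 lower in each chromium restriction array than in each control array, and the vertical axes do not start at 0.

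Several genes central to adipose and insulin action did not pass. Lep, which encodes leptin, was at 11.89 ± 0.13 against 11.91 ± 0.06, and the lipid carrier Fabp4 at 13.61 ± 0.09 against 13.65 ± 0.07 (SD, n = 3). Insr, the insulin receptor, differed by -0.36 ± 0.09, Irs1 by -0.31 ± 0.19, Akt2 by -0.44 ± 0.14 and the glucose transporter Slc2a4 by -0.78 ± 0.28 (SE, n = 3). In chromium restriction replicate 2, where liver transcripts were at control level, the difference from the control mean was -0.32 for Insr, -0.054 for Irs1, -0.24 for Akt2 and -0.14 for Slc2a4. With the liver genes as covariate it was -0.32, -0.052, -0.25 and -0.19. The insulin signalling list had 1 member past the test, Pdpk1, in a row with extra digits, and an adjusted p of 0.0726; the adipocyte identity list had 3 higher, Pparg, Retn and Cebpa, and 1 lower, Adipoq, all in such rows, and an adjusted p of 0.941. With an estimated correlation the adjusted p was 0.698 and 0.975. Without the rows with extra digits both lists passed downward with the preset correlation (adjusted p = 0.00695 and 0.0375), and with the liver genes as covariate as well both calls were lost (0.181 and 0.469). Insulin signalling also passed without chromium restriction replicate 2 (0.0438) or 3 (0.0160), without control replicate 2 (0.0220) and with quantile normalization (0.0424). Inflammatory cytokines and chemokines had an adjusted p of 0.0739, Tnf differed by 0.054 ± 0.10 and Ccl2 by 0.30 ± 0.13 (SE, n = 3). The list passed upward without the rows with extra digits (0.0114), in which Il6 lay, without control replicate 2 (0.0163), with median centring (0.0359), with the filter on dim genes (0.0094), and without the rows with extra digits and with the liver genes as covariate (0.0320). Ucp1, the uncoupling protein of brown fat, was at 10.25 in control replicate 1, at 7.37 in control replicate 3 and at 4.87 to 4.94 in the other 4 arrays, and the brown and beige list did not pass (adjusted p = 0.431). It passed downward without control replicate 2 (0.0184), and without the rows with extra digits and with the liver genes as covariate (0.0224).

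The other 15 lists tested did not pass. Among pathways the adjusted p was 0.112 for MAPK signalling, 0.905 for cholesterol synthesis, 0.375 for the interferon response, 0.102 for the unfolded protein response, 0.827 for metal handling, 0.833 for DNA and histone methylation enzymes and 0.530 for imprinted growth genes. Dnmt3b, in a row with extra digits, was the 1 member of these lists past the test over all genes. Among markers it was 0.876 for adipose progenitors and fibroblasts, 0.717 for granulocytes and mast cells, 0.104 for endothelial cells, 0.416 for mural and smooth muscle cells, 0.530 for epididymis and testis, 0.153 for gland epithelium, 0.833 for skeletal muscle and 0.827 for Schwann cells and nerve. The mean, the median and the test did not all have the same sign for cholesterol synthesis, metal handling, DNA and histone methylation enzymes, adipose progenitors, and Schwann cells. Without control replicate 1 endothelial markers passed upward (0.000235) and so did mural and smooth muscle markers (6.90e-05). MAPK signalling passed upward without chromium restriction replicate 1 (0.010) or control replicate 3 (0.0295), the unfolded protein response upward without control replicate 3 (0.00818), and the interferon response downward without control replicate 2 (0.0427). With the liver genes as covariate MAPK signalling (0.000158) and the unfolded protein response (0.0124) passed upward. Both results rest mostly on chromium restriction replicate 2, which also held intestinal and B lineage transcripts. In that replicate the mean log2 difference from the controls was 0.17 for MAPK signalling and 0.14 for the unfolded protein response. Whether RNA of other tissues gives these rises was not tested. With that covariate and without the rows with extra digits both passed again (0.000128 and 0.0115), and epididymis and testis markers passed downward (0.0439).

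Xist, expressed from the inactive X chromosome, was at 10.07 to 10.56 in all 6 arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty were at 4.50 to 5.20 in all 6. By these genes all 6 samples read as female, so a difference in sex between the groups is argued against.

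At an unadjusted p under 0.05 and at least 1.5-fold, 340 genes differed, 189 higher and 151 lower, and 52 of them lay in rows with extra digits. By unadjusted p alone 1319 genes were below 0.05, where 1109 would be expected by chance. Leaving out chromium restriction replicate 2 raised the adjusted count from 43 to 439, 325 higher and 114 lower. It raised the unadjusted count from 340 to 912. The group then held only replicates 1 and 3, both rich in liver transcripts. In that setting the liver gene Apoh differed by 5.15 (limma adjusted p = 0.00115). The mean of the pancreas and liver list was 1.88 there (camera adjusted p = 1.39e-07). How much of the higher counts comes from liver transcripts was not tested. Leaving out replicate 3 or any 1 control lowered the adjusted count to 24, and leaving out replicate 1 lowered the unadjusted count to 185.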

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

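All tests of explanations in this part were chosen after the results were seen. Probe sets without a single gene symbol were not part of the gene-level comparison. When all 33793 probe sets were tested, 8 without a single symbol passed an adjusted p of 0.05 in limma, 7 higher and 1 lower in the chromium restriction group than in the controls, and 7 of the 8 lay in rows with extra digits. The exception, a probe set of Snord14e and Hspa8 chosen after its values were seen, differed by 0.60 ± 0.06 (log2, SE, n = 3).

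Of the 43 called genes 40 lay in rows with extra digits, in which the groups differed by more and the replicates by less than elsewhere. Liver RNA in 2 arrays is argued against as the cause, since replicate 2, with liver transcripts at control level, differed from the controls as much as replicates 1 and 3 did (median ratio 1.01 over 64 rows, bootstrap 95% interval 0.988 to 1.04). The text of the values with extra digits shows that they were written differently from the rest of the table, but not how they were obtained. Whether they were computed or entered separately stays open. Of the 64 rows 2, Il6 and Retn, held values outside the range of all other values of their array. The largest count in 10000 random draws of 64 rows was also 2, and 2 lay above the 95th percentile of the draws. Such a count was thus uncommon among random rows, but it concerns only Il6 and Retn. Values entered separately can lie inside that range, so this count cannot decide. In 64 of the 64 rows the groups did not overlap, and the smallest absolute log2 difference was 0.599. An effect of maternal diet on these genes stays open, since other probe sets of the same genes, with a median ratio of -0.0575 to the shift of the row, cover 5 of 61 genes and may read other parts of the transcripts. Of the 10 splits of the 6 arrays into 3 and 3, the highest of the others gave 0 genes against 43, and 10 splits are too few for a share under 0.05 (1 of 10 gave as many).

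Chromium restriction replicates 1 and 3 were rich in liver transcripts. The rise was not shared by the group: in replicate 2 the median of the 7 liver genes was -0.52 relative to the control mean. These genes and arrays define the pattern, so this value describes it and is not a separate test of a diet effect. Whole liver samples in place of adipose are argued against by leptin, which in the lower of both arrays was 0.0183 above the control mean. Liver tissue RNA in these 2 adipose samples and a difference between animals that affects only 2 of them both stay open: 7 of the 7 liver genes were above the highest control in both arrays, but these genes define the pattern, so the count does not decide.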

How the results depend on the processing

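Alternatives that concern the rows with extra digits or the liver genes were chosen after seeing the data. The count of 43 genes past an adjusted p of 0.05 stayed between 42 and 53 with quantile normalization, median centring, the filter on dim genes, trend and robust options, array weights, the mean of a gene's probe sets, all probe sets and the liver covariate. With the liver covariate it was 53, 40 higher and 13 lower, against 20 and 23, and 27 of the 43 genes were among them. Under the other alternatives named, all probe sets aside, 39 to 43 of the 43 genes were called. The count was 0 in limma without the rows with extra digits (1264 genes at an unadjusted p under 0.05), 0 with the 183 values set to missing (1280), and 0 over all probe sets without those rows (1719). With fewer very small p-values the Benjamini-Hochberg threshold tightens, by construction. It was 6 without the rows with extra digits and with the liver score as covariate, and 6 without both arrays rich in liver transcripts, where 1 array stood against 3 and was assumed to vary like the controls. Leaving out each array in turn gave 24 to 439 genes. The count of 340 genes at an unadjusted p under 0.05 and 1.5-fold was 598 with array weights and 185 to 912 when leaving out each array, and the cause was not tested. The highest counts when leaving out an array, 439 and 912, came without chromium restriction replicate 2. The 2 arrays left in that group were those rich in liver transcripts. The count of 16 lists was 0 with an estimated correlation, and between 11 and 19 under the other alternatives.

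With the replicate number as a block 0 genes passed in limma, with 1337 at an unadjusted p under 0.05, and 19 lists passed, the 16 and also insulin signalling (adjusted p = 0.0410), inflammatory cytokines (0.0428) and endothelial markers (0.0384). The correlations of same-numbered arrays' deviations from their group means were -0.12, -0.0947 and 0.0782, each under a minimum of 0.1 for pairing. The deviations of the chromium restriction arrays also hold the liver and intestinal transcripts, so these values cannot exclude a pairing. The labels do not say whether same-numbered samples belong together. The block also leaves fewer residual degrees of freedom than the reported fit.

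Among the 10 splits into 3 and 3 the unadjusted count was 340 for the real groups and 347 for the highest other, which set chromium restriction replicates 1 and 3 with control replicate 1, and 2 of 10 splits gave as many. The lists passing were 16 for the real groups and 18 for the highest other, and 2 of 10 splits gave as many. With 10 splits no share under 0.05 can be reached.

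Of the 31 named genes past the threshold none turned direction under any alternative in which it was tested. The groups did not overlap in any of these genes, so leaving out arrays could not turn them. Only 3 of the 31 were tested without the rows with extra digits, and these 3 lost their call there. The direction turned for some named genes that were not past the threshold. With the liver score as covariate, with or without the rows with extra digits, the log2 difference was 0.0366 for Pdgfra, -0.0831 for Cldn5, 0.000503 for Myl1, -0.0938 for Apoh, 0.0313 for Mbp, 0.0257 for Scd1, 0.0292 for Lpl and -0.0596 for Tnf. Without both arrays rich in liver transcripts it was 0.0946 for Pdgfra, 0.0892 for Lyve1, -0.12 for Cldn5, 0.0441 for Myl1, -0.29 for Apoh, 0.0397 for Mbp, 0.0746 for Fasn, 0.0312 for Scd1, 0.0399 for Lpl and -0.0745 for Tnf. Fabp4 turned to 0.00823 with array weights, and Lpl to 0.45 with the mean of its probe sets, which takes in its row with extra digits. Leaving out each array gave -0.0275 to 0.68 for Bank1, -0.00683 to 0.32 for Fcer2a, -0.0119 to 0.31 for Tpsb2, -0.0672 to 0.0583 for Lep, -0.0836 to 0.00215 for Fabp4 and -0.00907 to 0.12 for Tnf. For lists past the threshold, the mean of de novo lipogenesis turned to 0.0131 with the liver score as covariate and 0.0667 without both arrays rich in liver transcripts. It did not turn with the covariate when the rows with extra digits, in which Srebf1 lay, were also left out (-0.0443). The pancreas and liver list turned to -0.0278 with that covariate, which is made of 7 of its 16 members, with or without the rows with extra digits. It turned to -0.11 without both arrays, which were left out for their liver transcripts. Leaving out each array gave -0.10 to 0.54 for B and plasma markers and -0.16 to 0.39 for mesothelium, which passed in both directions (adjusted p = 0.0215 at -0.16, without control replicate 1). The mean of T and NK markers was -0.0018 without chromium restriction replicate 2, although camera's direction stayed upward. Except where said, the cause was not tested. Dim probe sets limit what can be seen of genes near the array background, such as Il6 and Tnf.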

Other observations

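The tests in this part were chosen after the results were seen. In chromium restriction replicate 2, 14 of 20 genes of the intestinal epithelium had their highest value of the 6 arrays, and 7 of them were more than 1 log2 unit above every other array, among them the brush border genes Alpi at 7.24 and Sis at 7.09 and the keratin gene Krt20 at 7.54. The brown fat genes Cidea and Cox7a1 followed Ucp1 in control replicate 1, at 10.73 and 9.15, and were at 5.75 to 7.32 and 6.07 to 7.04 in the other 5 arrays. These genes were chosen after their values were seen.

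The clock genes were also set as a contrast, the mean of 5 genes that peak with Arntl minus the mean of 9 that peak with Dbp. It was -0.57 ± 0.16 in the chromium restriction group and -1.40 ± 0.22 in the controls (log2, SD, n = 3), an exact permutation p of 0.1, two-sided, the smallest that 3 arrays against 3 allow. Liver RNA as the whole cause is argued against by replicate 2, whose contrast lay 0.741 above the highest control, where the SD of the controls was 0.225. Replicate 2 held intestinal and B lineage transcripts instead, so RNA of other tissues in the chromium restriction arrays is not excluded. A different time of day at tissue collection may give such a difference and cannot be told apart from an effect of maternal diet on the clock, because no collection time is given in the sources used here and the exact p of 0.1 cannot go lower. Both stay open.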
